A study of Homo sapiens with 12 samples.

How the data were processed

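Human brain microvascular endothelial cells from a commercial supplier were transfected with siGlut1 or non-silencing siRNA and kept in control or high glucose. The labels give 12 samples in 4 groups of 3 replicate numbers. RNA was isolated with RNeasy columns, and the labels name 2 library kits for the same samples, TruSeq stranded mRNA and SMARTER, without saying which library was made with which. The submitters' processing notes name the build hg19 and the tool DESeq2, with no versions. The aligner, the counting tool, the use of strand in counting and the annotation are not given in the sources used here.

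The deposited table holds 23398 gene entries with hg19 coordinates and, for each sample, a count and an RPKM. The deposited counts are whole numbers per gene, not normalised, per the file headers and the values. The deposited RPKM values were computed by the authors from counts, gene length and a library total, and that total was 1.05 to 1.07 times the sum of the deposited counts. Of the gene lengths, 35.1% are multiples of 3, about what chance gives, so that they are not lengths of coding sequence alone. The table holds 0 entries of the mitochondrial genome. The counts were used for all tests, and the RPKM values only to check the columns. No column of values was without a sample in the labels (0).

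Each column was compared with the mean of the other 2 columns of its group. The column of non-silencing siRNA in high glucose, replicate 2, equals that mean in all but 1 entry, so it was left out. The fits therefore hold 11 libraries where the design fixed before the data were examined had 12, and the 12 columns were run as an added alternative. Before the fits 124 entries of the sex chromosomes were left out, so that nothing on a donor is reported, and 26 symbols that stand on more than 1 entry kept separate values. Total deposited counts per library ranged from 40135082 to 90536476 with a median of 49686182.

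Counts of 23274 entries were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 14324, and libraries were scaled by TMM, with factors of 0.975 to 1.03. All 4 groups were fitted in 1 quasi-likelihood model without a replicate block (7 residual degrees of freedom, median prior degrees of freedom 4.46, common dispersion 0.0161). Tests were two-sided quasi-likelihood F tests with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05, with no fold minimum. The standard error of a log2 fold change was taken as its size over the square root of F. CPM values, from edgeR's cpm function, used TMM-scaled library sizes, with a prior count of 2 where they were put on the log2 scale. The comparisons were siGlut1 against non-silencing siRNA in each medium, high against control glucose with each siRNA, their interaction, and the effects of siRNA and of glucose averaged over the other factor.

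Of 33 gene lists fixed beforehand, 28 had at least 5 tested members. They cover glucose transporters, glycolysis, pentose phosphate, polyol and hexosamine pathways, the TCA cycle, oxidative phosphorylation, mitochondrially encoded genes, MondoA and ChREBP targets, the integrated stress response, endoplasmic reticulum chaperones, hypoxia, cholesterol and fatty acid synthesis, endothelial identity, junctions, barrier transporters, NF-kB and interferon targets, S phase, mitosis, p53, matrix, Notch, NRF2, glycocalyx, lysosome and ribosomal proteins. Further lists hold markers of pericytes, fibroblasts, astrocytes, microglia and leukocytes, neurons and oligodendrocytes, epithelium and lymphatic endothelium. For each list and comparison the members past the threshold were counted over all genes tested and adjusted over the list alone, and limma 3.58.1 camera was run with a preset correlation of 0.01, adjusted over the lists of 1 comparison. Camera with an estimated correlation and fry, which asks whether a list moves on balance without comparing it with other genes, were run beside it.

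Genes were named by a rule fixed beforehand, extended to both averages after the data were seen. It takes SLC2A1, and the genes past the threshold with the largest log2 fold change, up to 8 per direction. Those genes needed a mean of at least 2 CPM and, in the pairwise comparisons but not in the averages, groups that do not overlap. Per list it takes up to 4 members past the threshold or, where none passes, the 2 members with most counts. It names 179 genes. Clone names and pseudogenes were left out. Overlap of calls between comparisons was set against the product of both counts over the genes tested, per direction. The covariance of the averaged effects was set against 20 simulations of unchanged libraries.

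The alternatives fixed beforehand were a replicate block, DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 6 libraries, a fit of only the 2 groups compared, a fold minimum of 2, and each library left out in turn. Where this left 1 library in a group, that library was assumed to vary like the others. Those added after the data were seen were the 12 columns, halved counts, the fits without both control-glucose replicates numbered 3, and an offset that removes each library's lowess trend (span 0.3) on gene length. Glucose genes for the check of control labels were those past the threshold with the other siRNA, fitted without both control-glucose replicates numbered 3, that moved the same way by over 0.2 on the log2 scale. The groups were also split in other ways, 10 splits of 6 libraries or 40 drawn splits of all 11. The scripts were tested on simulated data drawn from the means and library sizes of the real libraries with 200 changed genes, in 3 simulations. For siGlut1 in control glucose they recovered 71.3% of genes changed 1.5-fold, 96.7% of those changed 2-fold and 100% of those changed 3-fold and 4-fold, over 14155 genes, with 2.65% false calls. For high glucose with non-silencing siRNA they recovered 52%, 95.3%, 99.3% and 100% at these folds over 14156 genes, with 2.99% false calls. Changed genes had a mean of at least 2 CPM. The simulation held no structure between libraries, such as a trend on gene length or replicates numbered 3 that stand apart. Recovery in the real libraries may therefore be lower, and a count of 0 genes does not show that 2-fold changes are absent. A simulated changed list was called 1 of 1 time and unchanged lists 0 of 20 times. Without structure between libraries, list members did not vary together in the simulation. It therefore cannot check the preset correlation of camera for the real libraries, where 66 of 66 list calls ended with an estimated correlation.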

Results

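Messenger RNA was sequenced from human brain microvascular endothelial cells, the cells that line the small vessels of the brain and form the blood-brain barrier. SLC2A1 encodes the glucose transporter Glut1, which these cells use to carry glucose from the blood towards the brain. The cells were transfected for 48 h with an siRNA against SLC2A1 (siGlut1) or with a non-silencing siRNA, and were kept in control medium or in high glucose, whose concentration is not given in the sources used here. This gives 4 groups with 3 replicate numbers each and 12 columns of counts. Libraries are named below by siRNA, medium and replicate number, such as non-silencing control 1. The question behind the design was how suppression of Glut1 and high glucose, alone and together, change the transcripts of these cells.

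Deposited counts over genes totalled 49500006, 40135082 and 62209428 in non-silencing control 1, 2 and 3, and 50352046, 79130054 and 45399368 in siGlut1 control 1, 2 and 3. In high glucose they totalled 47548382 and 49686182 in non-silencing high 1 and 3, and 48652800, 58554674 and 90536476 in siGlut1 high 1, 2 and 3. All counts in these 11 columns were even, as they would be if each read pair was counted as 2. The 10 genes with most counts took 6.24% to 7.78% of a library.

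The column of non-silencing high 2 held no counts of its own. It equalled the mean of replicates 1 and 3 of its group in 23397 of 23398 entries for counts (the exception was ABCA4, with 68, 72 and 68) and in 23398 of 23398 for RPKM, within 1e-06. In the other 3 groups, 1.39% to 2.06% of expressed entries met this by coincidence. The column was therefore left out, and all comparisons rest on 11 libraries, with n = 2 for non-silencing siRNA in high glucose and n = 3 elsewhere. The groups, the tests, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined, and assumed 12 libraries. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14324 tested genes, and the threshold was 0.05. The replicates numbered 3 of both control-glucose groups stood apart from the other libraries of their groups. A chi-square per gene between replicates was 45.3 and 55.4 for the pairs with non-silencing control 3. It was 25 and 39.6 for those with siGlut1 control 3 and 10.9 to 20.9 for the other pairs of libraries, and it grows with depth. The root mean square distance from the rest of the group on log2 CPM separated them less. It was 0.475 for non-silencing control 3 and 0.451 for siGlut1 control 3, against 0.301 to 0.437 for the other libraries.

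SLC2A1 itself (chromosome 1, 43391046 to 43424847, hg19) was lower with siGlut1 in each library of both media. Its level was 25.7, 23.7 and 22.2 CPM (counts scaled for library size) in non-silencing control 1, 2 and 3, and 8.56, 9.05 and 6.26 CPM in siGlut1 control 1, 2 and 3. In high glucose it was 21.2 and 20.7 CPM in non-silencing high 1 and 3, and 7.09, 7.19 and 6.38 CPM in siGlut1 high 1, 2 and 3. The group means were 23.9 ± 1.74 (SD, n = 3) CPM against 7.96 ± 1.49 (SD, n = 3) CPM in control glucose and 20.9 ± 0.395 (SD, n = 2) CPM against 6.89 ± 0.443 (SD, n = 3) CPM in high glucose. The siRNA left 0.334 of the transcript in control glucose (log2 fold change -1.58 ± 0.13 SE, adjusted p = 0.000884) and 0.328 in high glucose (-1.61 ± 0.14 SE, adjusted p = 0.000888). Both calls held with any 1 library left out. High glucose gave -0.19 with non-silencing siRNA (adjusted p = 0.954) and -0.22 with siGlut1 (adjusted p = 0.458), neither past the threshold.

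**Figure D1:**
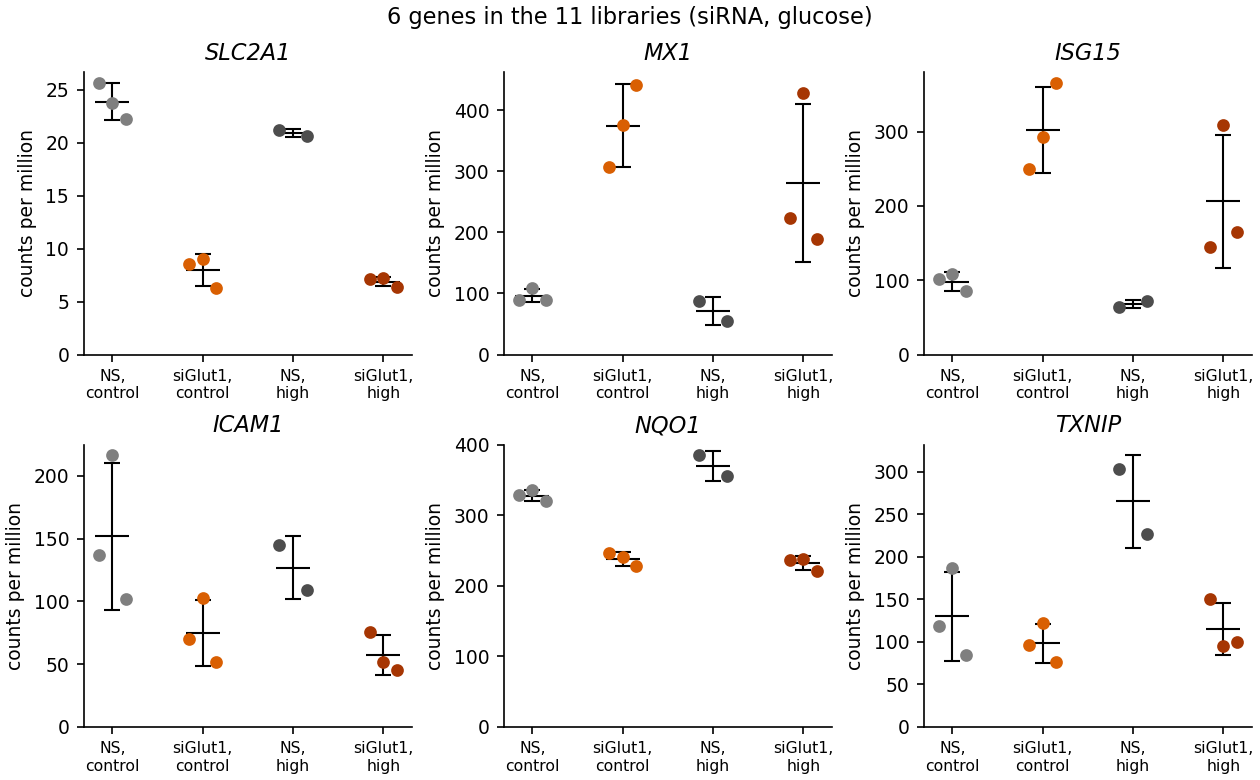
CPM (vertical axis) of SLC2A1, MX1, ISG15, ICAM1, NQO1 and TXNIP in each of the 11 libraries (points), by group, with the mean and SD as bars. SLC2A1 lay at 20.7 CPM or above in the 5 non-silencing libraries and at 9.05 CPM or below in the 6 siGlut1 libraries.

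Suppression of Glut1 in control glucose was accompanied by a rise of genes that interferon induces and by lower medians of the lists of NF-kB and NRF2 targets. MX2 and MX1, antiviral GTPases, rose by 2.74 ± 0.47 and 1.96 ± 0.28 SE on the log2 scale, 6.67 and 3.89 fold (n = 3 per group). RSAD2, which makes an antiviral nucleotide, CMPK2, a mitochondrial nucleotide kinase, IFIT1, which binds viral RNA, and IFITM1, which hinders viral entry, rose by 2.61, 2.40, 1.98 and 2.05. IFI44L rose by 1.75 ± 0.23 SE (adjusted p = 0.00529), and ISG15, a ubiquitin-like protein modifier, by 1.62 ± 0.25 SE (adjusted p = 0.0086). Of 35 tested interferon-stimulated genes, 24 rose and 0 fell over all genes tested, 33 rose adjusted over the list alone, and all 35 had a positive log2 fold change, with a median of 1.16. Camera gave the list an adjusted p of 3.69e-54 (adjusted p = 0.159 with an estimated correlation). The 24 rising members became 6 without non-silencing control 1, 13 without siGlut1 control 2, 14 without siGlut1 control 3 and 8 without both control-glucose replicates numbered 3, and the calls of MX2, RSAD2, CMPK2, IFIT1 and IFITM1 ended without non-silencing control 1 (2.75, 2.42, 2.31, 1.83 and 2.04, with adjusted p-values of 0.0593, 0.0744, 0.0668, 0.0550 and 0.0932). The IFITM1 call also ended without non-silencing control 3 (1.89) or siGlut1 control 1 (2.07), 2 (2.11) or 3 (1.96). Members of the IFIT, IFITM and MX families resemble each other in sequence, so that reads could be shared among them.

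Inflammatory genes driven by NF-kB had the lowest median of the tested lists in control glucose with siGlut1. CCL20, a chemokine that attracts lymphocytes, fell from 0.761 ± 0.467 (SD, n = 3) CPM to 0.0706 ± 0.0493 (SD, n = 3) CPM (-3.28 ± 0.66 SE, adjusted p = 0.0262), close to the floor of detection. NFKB2, a subunit of NF-kB, fell by 0.56 (adjusted p = 0.0441). These were the 2 of 30 tested members past the threshold over all genes, with 12 lower when adjusted over the list alone, and the median was -0.56 (camera adjusted p = 5.5e-10; adjusted p = 0.159 with an estimated correlation). ICAM1, an adhesion molecule for leukocytes, gave -1.02 ± 0.30 SE (adjusted p = 0.0967) and BIRC3, an inhibitor of cell death, -0.75 (adjusted p = 0.1), both short of the threshold. Calls of NFKB2 ended without non-silencing control 1 or 2 or any siGlut1 control library, and those of CCL20 without non-silencing control 3 or any siGlut1 control library, with adjusted p-values of 0.0543 to 0.134 for NFKB2 and 0.0511 to 0.0927 for CCL20. The 2 members became 7 with DESeq2, 8 with the replicate block and 0 with only the 2 groups compared.

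Among single genes with the strongest falls in control glucose were UHMK1, a kinase that phosphorylates a cell cycle inhibitor (-0.93 ± 0.09 SE, adjusted p = 0.000923), and PHLDA2, an imprinted growth regulator (-1.10 ± 0.17 SE, adjusted p = 0.00965). ABAT, which breaks down the transmitter GABA, gave -1.10 ± 0.22 SE, the motor MYO5B -0.92, the lysosomal protease CTSS -0.85 and the glutathione transferase GSTM4 -0.95, all past the threshold. GSTM4 belongs to a family of near-identical genes that could share reads. Of 24 genes of the NRF2 antioxidant response, 4 fell over all genes tested and 5 adjusted over the list alone. They were PIR (-0.78), the quinone reductase NQO1 (-0.46 ± 0.06 SE, adjusted p = 0.00637), the thioredoxin reductase TXNRD1 (-0.40) and the sulfiredoxin SRXN1 (-0.32). The list's median was -0.14 (camera adjusted p = 0.00385; adjusted p = 0.273 with an estimated correlation), and its call ended without non-silencing control 3 (median -0.062, adjusted p = 0.107). The 4 became 2 without non-silencing control 1 or 3 or siGlut1 control 2. GLO1, which detoxifies methylglyoxal formed from glucose, fell by 0.46 (adjusted p = 0.00646). ASNS, which makes asparagine, fell by 0.80 (adjusted p = 0.007). ZMAT3, a target of p53, and XYLT2, which starts heparan sulfate chains, were lower with log2 fold changes of -0.72 and -0.68. UHMK1, PHLDA2, GSTM4, NQO1, GLO1, ASNS, ZMAT3, XYLT2, MX1, ISG15 and IFI44L kept their calls in each alternative run other than the fold minimum of 2, which was applied to counts of genes only.

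Camera called 5 more lists in control glucose with few or no single genes past the threshold, and none of these calls held with an estimated correlation. TAGLN, an actin-binding protein of contractile cells, rose by 1.26, the growth factor TGFB2 by 0.69, the adhesion protein CDH2 by 0.55 and CTGF by 0.40. With these 4 genes of 40, the matrix and mesenchymal list had a median of 0.11 (camera adjusted p = 0.00133; adjusted p = 0.732 with an estimated correlation), and 6 rose adjusted over the list alone. The lysosomal protease CTSB rose by 0.35. In all, 2 of 31 lysosomal genes rose, and 5 adjusted over the list alone (median 0.10, camera adjusted p = 0.0132; adjusted p = 0.732 with an estimated correlation). None of 35 mitosis genes passed the threshold, over all genes tested or adjusted over the list alone, and their median was -0.29 (camera adjusted p = 1.51e-06; adjusted p = 0.732 with an estimated correlation). Of 22 Notch and tip or stalk genes, 0 rose over all genes and 5 adjusted over the list alone (median 0.21, camera adjusted p = 0.0376; adjusted p = 0.675 with an estimated correlation). Of 17 pentose phosphate, polyol and hexosamine genes, GLO1 fell over all genes and 3 adjusted over the list alone (median -0.075, camera adjusted p = 0.0376; adjusted p = 0.478 with an estimated correlation). All 5 of these list calls ended without non-silencing control 3, with medians of 0.065 for matrix, 0.084 for lysosome, -0.13 for mitosis, 0.067 for Notch and -0.058 for pentose genes. The lysosome and Notch calls also ended without siGlut1 control 1 (0.078 and 0.17) or siGlut1 control 2 (0.0705 and 0.10), and the pentose call without non-silencing control 1 (-0.069) or siGlut1 control 2 (-0.047).

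In all, 424 of 14324 genes passed the threshold in control glucose, 244 higher and 180 lower with siGlut1. Their median absolute log2 fold change was 0.48, and 51 changed at least 2-fold. All 424 had the 3 libraries of 1 group above those of the other, as did 20.6% of all tested genes, against the 10% that chance gives for 3 against 3. The count fell to 142 without non-silencing control 1, 135 without siGlut1 control 1, 164 without siGlut1 control 2 and 195 without siGlut1 control 3. It was 70 with only the 2 groups compared, 247 without both control-glucose replicates numbered 3 and 1049 with DESeq2. Of the 39 named genes past the threshold, 23 lost their call without non-silencing control 1, 10 and 15 without non-silencing control 2 and 3, and 19, 20 and 16 without siGlut1 control 1, 2 and 3, with adjusted p-values up to 0.162 and no change of sign.

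The same comparison in high glucose asked what suppression of Glut1 does when glucose is plentiful. Interferon-stimulated genes were again higher, and a few NF-kB and NRF2 targets, 2 of 30 and 5 of 24, and the thioredoxin inhibitor TXNIP were lower. MX2 rose by 2.98 ± 0.58 SE (adjusted p = 0.0213), RSAD2 by 2.75, CMPK2 by 2.56, IFITM1 by 2.07, IFIT1 by 2.0 and MX1 by 1.99 ± 0.33 SE (adjusted p = 0.0114), with n = 2 against n = 3. Of 35 interferon-stimulated genes, 17 rose and 0 fell over all genes tested, and 30 rose adjusted over the list alone (median 1.06, camera adjusted p = 2.39e-31; adjusted p = 0.206 with an estimated correlation). The 17 became 3 without non-silencing high 1, 0 without non-silencing high 3 and 9 without siGlut1 high 2, with medians of 1.32, 0.98 and 0.76. BIRC3 (-1.16) and NFKB2 (-0.72) fell, the 2 of 30 NF-kB genes past the threshold (11 with the replicate block). Adjusted over the list alone, 10 fell (median -0.62, camera adjusted p = 5.25e-09; adjusted p = 0.16 with an estimated correlation). The 2 became 0 without non-silencing high 1 or 3 or siGlut1 high 3, and 1 without siGlut1 high 1 or 2, with medians of -0.61 to -0.68, and rose to 7 with DESeq2, 11 with only the 2 groups compared and 10 without both control-glucose replicates numbered 3.

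Some genes of the NRF2 list and of the pentose phosphate, polyol and hexosamine list fell with siGlut1 in high glucose. NQO1 fell by 0.67 (adjusted p = 0.00162), and PIR (-1.02) and TXNRD1 (-0.45) fell too. SRXN1 (-0.34) was lower as well. In all, 5 of 24 NRF2 genes fell and 6 did adjusted over the list alone (median -0.18, camera adjusted p = 1.18e-05; adjusted p = 0.16 with an estimated correlation). The 5 became 2 and 1 without non-silencing high 1 and 3, and 3, 2 and 2 without siGlut1 high 1, 2 and 3. TKT, an enzyme of the pentose phosphate pathway, and GLO1 fell, with -0.38 and -0.54. In the pentose phosphate, polyol and hexosamine list 3 of 17 fell, 5 adjusted over the list alone (median -0.14, camera adjusted p = 0.000517; adjusted p = 0.16 with an estimated correlation). TXNIP, a glucose-induced gene that limits glucose uptake, was at 265 ± 54.7 (SD, n = 2) CPM with non-silencing siRNA and 115 ± 30.4 (SD, n = 3) CPM with siGlut1 (-1.21 ± 0.30 SE, adjusted p = 0.0494), and was the only 1 of 10 glucose-responsive MondoA and ChREBP targets past the threshold. Lower too were ASNS (-1.02), the transporter ABCC3 (-1.43), ABAT (-1.46), GSTM4 (-1.24), SELENBP1 (-1.21) and the amino acid transporter SLC7A8 (-1.17). XYLT2 fell by 0.96 (adjusted p = 0.000888).

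Transcripts for respiration, translation and sterol synthesis were slightly lower with siGlut1 in high glucose, as lists more than as single genes. Of 48 nuclear genes of oxidative phosphorylation, only UQCRQ, of complex III, fell (-0.39), with 4 lower adjusted over the list alone (median -0.14, camera adjusted p = 5.64e-06; adjusted p = 0.298 with an estimated correlation). RPL5 (-0.33) and RPL4 (-0.28) fell, 2 of 53 ribosomal protein genes and 2 adjusted over the list alone (median -0.14, camera adjusted p = 6.75e-06; adjusted p = 0.449 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes. HMGCS1 (-0.53) and FDFT1 (-0.40), enzymes of cholesterol synthesis, fell, 2 of 21 and 4 adjusted over the list alone (median -0.11, camera adjusted p = 0.00243; adjusted p = 0.449 with an estimated correlation). SDHC, of complex II, fell by 0.31, 1 of 22 TCA cycle genes and 4 adjusted over the list alone (median -0.11, camera adjusted p = 0.00689; adjusted p = 0.332 with an estimated correlation). HERPUD1 fell by 0.28, 1 of 20 chaperone genes and 3 adjusted over the list alone (median -0.16, camera adjusted p = 0.0042; adjusted p = 0.277 with an estimated correlation). In high glucose, log2 fold changes with siGlut1 also rose with gene length across genes (Spearman's rho 0.24). Removing each library's trend on length ended the calls of the oxidative phosphorylation (median -0.039, adjusted p = 0.081), ribosomal (-0.032, adjusted p = 0.241) and TCA cycle lists (-0.083, adjusted p = 0.0755). The TCA cycle and chaperone calls also ended without non-silencing high 1 (-0.040 and -0.11).

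A few matrix and tip cell genes rose in the same comparison. RELN, a secreted matrix protein, rose by 1.73 ± 0.29 SE, the netrin receptor UNC5C by 1.90 and the proteoglycan VCAN by 1.79. TAGLN rose by 1.47, TGFB2 by 0.76 and CDH2 by 0.74, while TIMP1, an inhibitor of matrix proteases, fell by 0.36. The matrix list had 3 higher and 1 lower of 40, or 7 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 0.000517; adjusted p = 0.486 with an estimated correlation). The chemokine receptor CXCR4 and the Notch ligand JAG1 rose by 0.70 and 0.35, 2 of 22 Notch and tip or stalk genes and 4 adjusted over the list alone (median 0.24, camera adjusted p = 0.00654; adjusted p = 0.298 with an estimated correlation). This call ended without non-silencing high 1 (0.27, adjusted p = 0.0658). FLT1 and KDR, receptors for the endothelial growth factor VEGF, rose by 0.72 and 0.44, and the endothelial transcription factor FLI1 fell by 0.53. None of 35 mitosis genes passed the threshold, over all genes tested or adjusted over the list alone (median -0.16, camera adjusted p = 0.00944; adjusted p = 0.802 with an estimated correlation). The list's call ended without non-silencing high 1 (-0.18), siGlut1 high 1 (-0.12) or siGlut1 high 3 (-0.14), and with the replicate block (-0.085).

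In all, 589 of 14324 genes passed the threshold in high glucose, 354 higher and 235 lower with siGlut1, with a median absolute log2 fold change of 0.52 and 90 genes changed at least 2-fold. All 589 had the libraries of 1 group above those of the other, as did 44.5% of all tested genes, against the 20% that chance gives for 2 against 3. The count was 1157 with only the 2 groups compared, 1319 with DESeq2 and 1672 without both control-glucose replicates numbered 3. The count fell to 31 without non-silencing high 1, 6 without non-silencing high 3, 261 without siGlut1 high 1, 130 without siGlut1 high 2 and 161 without siGlut1 high 3. Of the 54 named genes past the threshold, 49 lost their call without non-silencing high 1, 52 without non-silencing high 3 and 24, 34 and 33 without siGlut1 high 1, 2 and 3, with adjusted p-values up to 0.317 and no change of sign, and NQO1 and XYLT2, both changed less than 2-fold, kept theirs in each alternative run other than the fold minimum.

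The siGlut1 effect had the same direction in both media, 2 comparisons that share no library. Of the genes past the threshold, 156 were higher and 104 lower in both, against 6.03 and 2.95 for independent lists, and 0 went opposite ways. The 260 shared calls became 29 without non-silencing high 1 and 6 without non-silencing high 3, and lay between 101 and 161 without siGlut1 high 1, 2 or 3, non-silencing control 1 or siGlut1 control 1, 2 or 3. Across the 14324 genes the log2 fold changes had a Pearson r of 0.54, a Spearman rho of 0.59 and a covariance of 0.0805, a description across genes, which are not independent replicates. The r became 0.35 without non-silencing high 1 and 0.33 without non-silencing high 3. These fits left 1 library in that group and tested 14656 and 14633 genes. As r also depended on the filter (0.10 without one, 0.76 with a stricter one), the drop cannot be laid to the left-out library alone. In the other medium, 422 of the 424 genes (99.5%) and 586 of the 589 kept their sign.

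Averaged over the media, siGlut1 moved 2065 genes past the threshold, 1136 higher and 929 lower, with 136 changed at least 2-fold. In 1103 of them all siGlut1 libraries lay on 1 side of all non-silencing libraries, as in 8.71% of all tested genes. Naming genes of this average, and of the average effect of high glucose, by the ranking rule of the single comparisons was an extension made after the data were seen. In the averages the rule did not ask for groups without overlap. 32 of 35 interferon-stimulated genes rose, and all 35 adjusted over the list alone, with XAF1, a promoter of cell death, at 1.62 (median 1.16, camera adjusted p = 1.58e-46; adjusted p = 0.121 with an estimated correlation). 12 of 30 NF-kB genes fell (22 with the replicate block), 22 adjusted over the list alone (median -0.67, camera adjusted p = 7.21e-11; adjusted p = 0.121 with an estimated correlation). The 12 became 7 without non-silencing high 1 and 19 without non-silencing control 3 or without both control-glucose replicates numbered 3. ICAM1 fell by 1.08 (adjusted p = 0.00896), as did VCAM1, its partner in leukocyte adhesion (-1.86), BIRC3 (-0.95) and CCL20 (-2.73). HES4 and HEY2, transcription factors downstream of Notch, rose by 1.25 and 1.07, with 6 of 22 Notch and tip or stalk genes past the threshold and 9 adjusted over the list alone (camera adjusted p = 0.01; adjusted p = 0.415 with an estimated correlation). FTH1, the heavy chain of ferritin, fell by 0.40, with 7 of 24 NRF2 genes lower (camera adjusted p = 8.89e-05; adjusted p = 0.121 with an estimated correlation). The 2065 genes became 1020 without non-silencing high 1, 1001 without non-silencing high 3 and 1375 without siGlut1 high 2. Of 93 named genes of this average, 33 lost their call without non-silencing high 1 and 25 without non-silencing high 3, among them VCAM1 (-1.64) and HES4 (1.23) without non-silencing high 1. The HEY2 call ended without any 1 of 7 libraries (0.81 to 1.25).

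**Figure D2:**
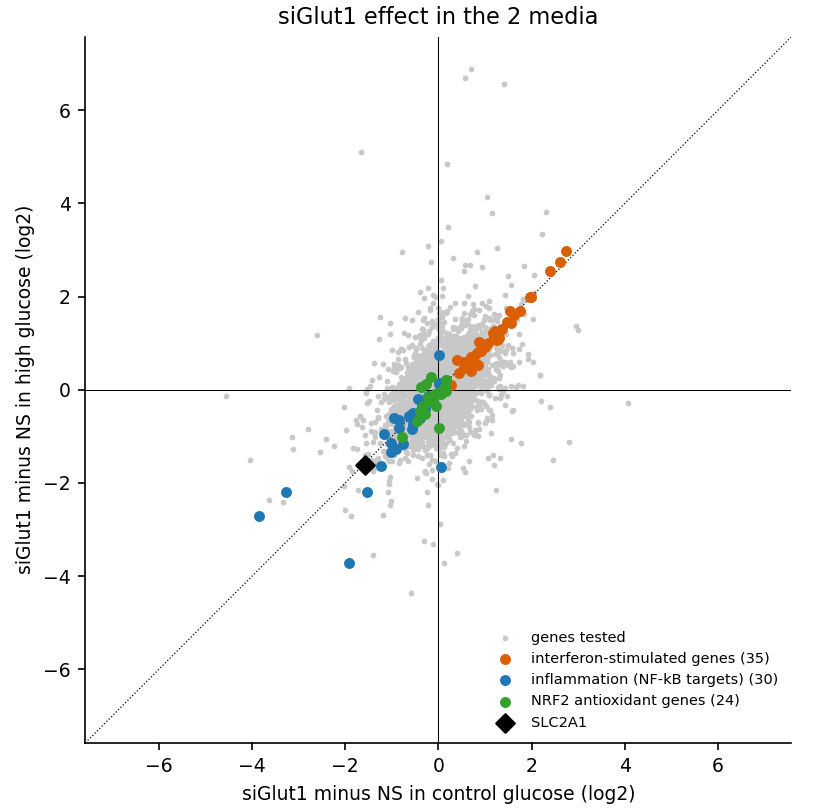
Log2 fold change of siGlut1 against non-silencing siRNA in control glucose (horizontal axis) and in high glucose (vertical axis) for the tested genes, with 35 interferon-stimulated, 30 NF-kB and 24 NRF2 genes and SLC2A1 marked, and a dotted line where both are equal. Genes lay along that line with a Pearson r of 0.54, and the interferon-stimulated genes had medians of 1.16 and 1.06.

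High glucose alone, with non-silencing siRNA, was compared with control glucose in cells with their Glut1. The group labels name no osmotic control, so effects of osmolality were not told apart from those of glucose. No single gene passed the threshold with edgeR (0 of 14324, smallest adjusted p = 0.261), while 774 genes (5.4%) had an unadjusted p under 0.05 and DESeq2 called 33. TXNIP, the glucose-induced inhibitor of thioredoxin, was at 130 ± 52.3 (SD, n = 3) CPM in control and 265 ± 54.7 (SD, n = 2) CPM in high glucose (1.03 ± 0.30 SE, adjusted p = 0.777). MCTP1, a calcium-binding membrane protein, gave 0.50 (adjusted p = 0.261), and KIAA1274 -1.29 (adjusted p = 0.272). The share of genes with groups that did not overlap was 17.8%, against 20% by chance. The count became 2 without non-silencing control 3, and 48 without both control-glucose replicates numbered 3.

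As lists, with 0 members past the threshold in each, interferon-stimulated genes were lower in high glucose with non-silencing siRNA (median -0.29, camera adjusted p = 2.88e-05; adjusted p = 0.694 with an estimated correlation). This call ended without non-silencing high 3 (-0.099, adjusted p = 0.539). Ribosomal protein genes had a median of -0.091 (camera adjusted p = 8.22e-05; adjusted p = 0.584 with an estimated correlation), a call that ended without non-silencing control 2 (-0.027), and the median was -0.048 (adjusted p = 0.0163) once each library's length trend was removed. Medians of 0.11 for endoplasmic reticulum chaperones, 0.10 for pentose phosphate, polyol and hexosamine genes and 0.09 for NRF2 genes went with camera adjusted p-values of 0.000162, 0.000498 and 0.000498 (adjusted p = 0.15, 0.15 and 0.15 with an estimated correlation). Cholesterol synthesis genes gave 0.091 (adjusted p = 0.000512), TCA cycle genes 0.076 (adjusted p = 0.0047) and mitosis genes 0.053 (adjusted p = 0.0435), with adjusted p = 0.459, 0.459 and 0.941 with an estimated correlation. Targets of ATF4 in the stress response gave -0.13 (adjusted p = 0.0109), NF-kB genes -0.24 (adjusted p = 0.0183) and Notch genes -0.18 (adjusted p = 0.0269), with adjusted p = 0.46, 0.584 and 0.459 with an estimated correlation. Adjusted over the list alone, 2 cholesterol genes were higher. Of these 6, the TCA cycle call ended without non-silencing high 1 (0.032). The cholesterol call ended without non-silencing high 3 (0.087) or non-silencing control 2 (0.014). The stress response call ended without non-silencing high 3 (-0.098), non-silencing control 1 (-0.080) or 3 (-0.14), and the NF-kB call without non-silencing high 3 (-0.10), non-silencing control 2 (-0.11) or 3 (-0.38). The Notch call ended without non-silencing high 1 (-0.11), non-silencing control 1 (-0.17) or 2 (-0.077), and the mitosis call without non-silencing high 1 (0.041) or 3 (0.076), turning to -0.097 without non-silencing control 2. The NF-kB call also ended with a stricter filter (-0.23) or without both control-glucose replicates numbered 3 (-0.38), and the mitosis call with 12 columns (0.058). With the replicate block the NF-kB (-0.059), Notch (-0.11) and mitosis calls (-0.0053) ended. The interferon median was -0.48 without non-silencing high 1 and -0.19 without non-silencing control 2.

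In cells with siGlut1, high glucose raised ABI3BP, an extracellular matrix protein that binds collagen, by 0.90 ± 0.10 SE (adjusted p = 0.0217), from 50.3 ± 5.33 (SD, n = 3) CPM to 93.6 ± 7.22 (SD, n = 3) CPM. MCTP1 rose by 0.55 ± 0.07 SE (adjusted p = 0.0217). These were the 2 genes past the threshold, and each call ended with any of the 6 libraries left out, with log2 fold changes of 0.83 to 0.98 for ABI3BP and 0.50 to 0.58 for MCTP1 and adjusted p-values of 0.0731 to 0.148. Of all genes, 2176 had an unadjusted p under 0.05, 22.5% had groups that did not overlap (10% by chance), and DESeq2 called 432. Ribosomal protein genes were lower as a list, with 0 of 53 past the threshold over all genes and 47 adjusted over the list alone (median -0.25, camera adjusted p = 1.09e-31; adjusted p = 0.214 with an estimated correlation), and the median shrank to -0.10 once each library's length trend was removed. Oxidative phosphorylation genes had a median of -0.13 and interferon-stimulated genes of -0.35 (camera adjusted p = 5.34e-07 and 5.41e-07; adjusted p = 0.5 and 0.865 with an estimated correlation). The interferon median was -0.59 without siGlut1 high 2 and -0.20 without siGlut1 high 3 or siGlut1 control 3. Mitosis and S-phase genes gave 0.15 and 0.17 (camera adjusted p = 0.000346 and 0.00214; adjusted p = 0.865 and 0.865 with an estimated correlation), and both calls ended without siGlut1 high 2 (0.069 and 0.079) or siGlut1 control 2 (0.046 and 0.055). NF-kB genes gave -0.36 and stress response genes -0.11 (camera adjusted p = 0.0151 and 0.0346; adjusted p = 0.852 and 0.852 with an estimated correlation). The NF-kB call ended without siGlut1 high 3 (-0.26) or siGlut1 control 2 (-0.093), and the stress response call without siGlut1 high 1 (-0.082), siGlut1 high 3 (-0.12) or siGlut1 control 3 (-0.10), or without both control-glucose replicates numbered 3 (-0.094). Log2 fold changes rose with gene length across genes (Spearman's rho 0.38), and removing each library's length trend turned the oxidative phosphorylation median to 0.024 (adjusted p = 0.878). Without both control-glucose replicates numbered 3 the count of genes was 734.

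Averaged over the siRNAs, high glucose moved 59 genes past the threshold, 36 higher and 23 lower, with single genes of the matrix, of the hexosamine pathway and of amino acid transport among them. In 44 of the 59 all high-glucose libraries lay on 1 side of all control-glucose libraries, as in 1.74% of all tested genes. TNFSF15, a cytokine that restrains vessel growth, rose by 0.94 ± 0.16 SE (adjusted p = 0.0436), the chaperone HSPA2 by 0.74 (adjusted p = 0.0122), the matrix protease TLL1 by 0.68, ABI3BP by 0.67, the collagen COL8A1 by 0.61 and the retinoic acid receptor RARB by 0.60. GFPT1, which leads glucose into the hexosamine pathway, rose by 0.33, the amino acid transporter SLC38A2 by 0.32 and LOX, which crosslinks collagen, by 0.34. KIAA1274 fell by 1.17 (adjusted p = 0.0122), and the basement membrane protein NID2 (-0.73), the growth factor MDK (-0.64), LOXL1, a relative of LOX (-0.64), and the transcription factor CEBPB (-0.60) fell too. TXNIP gave 0.63 (adjusted p = 0.186). Ribosomal protein genes were lower as a list (median -0.17, 1 past the threshold, 44 adjusted over the list alone, camera adjusted p = 1.14e-21; adjusted p = 0.388 with an estimated correlation). Log2 fold changes of this average rose with gene length across genes (Spearman's rho 0.26). Removing each library's length trend shrank the ribosomal median to -0.048 with non-silencing siRNA and -0.10 with siGlut1. At an unadjusted p under 0.05 there were 2425 genes, and DESeq2 called 541. The 59 genes became 0 without non-silencing high 3, 2 without non-silencing high 1 or siGlut1 high 3, 6 without siGlut1 high 1, 14 without siGlut1 high 2, 5 without non-silencing control 1, 19 without non-silencing control 2, 12 without siGlut1 control 2, 25 without siGlut1 control 3 and 38 without siGlut1 control 1. They became 850 without non-silencing control 3, and 2580 without both control-glucose replicates numbered 3. Of the 20 named genes, 0 kept the call with each library left out, 20 and 19 lost it without non-silencing high 3 and 1, and adjusted p-values reached 0.273.

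The effects of high glucose with either siRNA, which share no library, had a Pearson r of 0.34 and a Spearman rho of 0.43 across genes, with 0 genes past the threshold in both. The r became 0.16 without non-silencing high 1 and 0.23 without non-silencing high 3. The average effects of siGlut1 and of high glucose were nearly unrelated across genes (r -0.07, rho -0.04). On log2 CPM their covariance was -0.00311, against a mean of -0.00354 in 20 simulations of unchanged libraries (range -0.00441 to -0.00296). Those simulations held no structure between libraries, so the real range may be wider. Of genes past both thresholds, 11 were higher in both (2.86 for independent lists) and 3 lower in both (1.49). Another 3 were higher with siGlut1 and lower in high glucose (1.82) and 4 the other way round (2.33). Both averages use the same estimate of each gene's spread, so overlap above these products does not by itself show a relation. The r ranged from -0.44 without non-silencing high 3 to 0.10 without non-silencing control 3, and was -0.31 without non-silencing high 1. Fits without non-silencing high 1 or 3 left 1 library in that group and tested 14656 and 14633 genes. Their r values therefore also reflect the changed set of genes.

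Whether siGlut1 acted differently in the 2 media was tested by the interaction of siRNA and glucose. No gene passed the threshold with edgeR (0 of 14324, smallest adjusted p = 0.999), 394 (2.75%) had an unadjusted p under 0.05, and DESeq2 called 0. For TXNIP, where siGlut1 gave -0.40 in control and -1.21 in high glucose, the interaction was -0.81 ± 0.41 SE (adjusted p = 0.999). The interferon-stimulated genes had a median interaction of -0.051 (camera adjusted p = 0.332). Oxidative phosphorylation and ribosomal protein genes had interactions below 0 as lists, with medians of -0.14 (camera adjusted p = 4.85e-12; adjusted p = 0.387 with an estimated correlation) and -0.16 (camera adjusted p = 8.81e-18; adjusted p = 0.387 with an estimated correlation). Interaction estimates also rose with gene length (Spearman's rho 0.39), and removing each library's length trend shrank these medians to -0.029 (adjusted p = 0.0477) and -0.042 (adjusted p = 0.00529).

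Genes of glucose uptake and glycolysis changed little as groups. SLC2A3, another glucose transporter of these cells, lay at 60.0 to 79.3 CPM across the 11 libraries. SLC2A1 lay at 20.7 to 25.7 CPM in the non-silencing libraries, though CPM is not scaled for gene length. SLC2A3 rose with siGlut1 in control glucose by 0.30 (adjusted p = 0.0432). That call ended with any 1 of the 6 libraries left out, with adjusted p-values of 0.0607 to 0.148. SLC2A14, a near-identical copy of SLC2A3, could share its reads. With SLC2A1 lower and SLC2A3 higher of 10 glucose transporters, the list gave a median of -0.13 (camera adjusted p = 0.162) in control glucose and, with SLC2A1 alone past the threshold, -0.12 (adjusted p = 0.0824) in high glucose. None of 23 glycolysis genes passed in either medium, with medians of 0.013 and 0.044 (camera adjusted p = 0.65 and 0.712), and GAPDH and ENO1 gave 0.10 and -0.0079 in control glucose. Targets of MondoA and ChREBP gave -0.022 and 0.041 (adjusted p = 0.878 and 0.712), hypoxia genes 0.091 and 0.048 (adjusted p = 0.953 and 0.5) with SLC2A1 the member past the threshold. Fatty acid and lipid storage genes gave 0.064 and 0.12 (adjusted p = 0.307 and 0.0834), where PLIN2, a coat protein of lipid droplets, rose by 0.43 and 0.39.

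Genes of endothelial identity and of the barrier moved singly with siGlut1. FLI1 fell in both media, with -0.48 and -0.53 in control and high glucose, in a list of 29 with medians of 0.10 and 0.066 (camera adjusted p = 0.132 and 0.184). In the junction list of 22, CDH2 rose and CLDN11, a tight junction protein, fell (-0.42 and -0.43; list adjusted p = 0.827 and 0.712). SLC6A6, which carries taurine, fell in both media (-0.65 and -0.59), in the list of 26 barrier transporters (adjusted p = 0.797 and 0.5). In high glucose ABCC5, an efflux pump, rose by 0.38 and SLC1A1, a glutamate transporter, fell by 0.33. The glycocalyx list of 25, with XYLT2 lower in both media and the core protein SDC2 higher by 0.59 in high glucose, gave adjusted p-values of 0.827 and 0.712. In the stress response list of 30, ASNS and SHMT2, a mitochondrial enzyme of serine use (-0.28 and -0.29), fell in both media (list adjusted p = 0.163 and 0.173). Targets of p53, with ZMAT3 lower in control glucose and SESN1 and DDB2 lower in high glucose (-0.38 and -0.31), gave 0.455 and 0.184. S-phase genes gave 0.163 and 0.712 with 0 members past the threshold in both.

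Some markers of other cell types were strongly expressed, others weakly, and few changed. The rule for named genes takes members past the threshold or with most counts, so it favours strongly expressed ones. Across the 11 libraries RGS5 and ANPEP of the pericyte list lay at 1491 to 2421 CPM and 1324 to 1971 CPM, GJA1 of the astrocyte list at 346 to 445 CPM and the epithelial keratin KRT18 at 231 to 286 CPM. Of 8 tested pericyte and smooth muscle markers, RGS5 fell by 0.34 in control glucose and ANPEP rose by 0.38 in high glucose (list adjusted p = 0.827 and 0.712). Of 11 fibroblast markers 8 were tested, among them COL1A2 at 4.32 to 37.1 CPM and FAP at 1.85 to 4.54 CPM. None of the 8 passed (list adjusted p = 0.986 and 0.955). Of 5 neuron and oligodendrocyte markers, the tubulin TUBB3, also found in cultured endothelium, rose by 0.66 in high glucose (adjusted p = 0.23 and 0.365). Too few members were expressed to test astrocyte markers (1, GJA1), microglia and leukocyte markers (3, with CD68 at 0.31 and CD14 at -0.21 in control glucose, neither past the threshold), epithelial markers (4, KRT18 and KRT19 among them) and lymphatic endothelial markers (4, of which FLT4 rose by 0.51 in control glucose). KRT19 lay at 109 CPM in non-silencing control 3 and 110 CPM in siGlut1 control 3, against 33.6 to 55.4 CPM in the other 9 libraries, and was singled out after its values were seen. None of 13 mitochondrially encoded genes had an entry in the table.

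**Figure D3:**
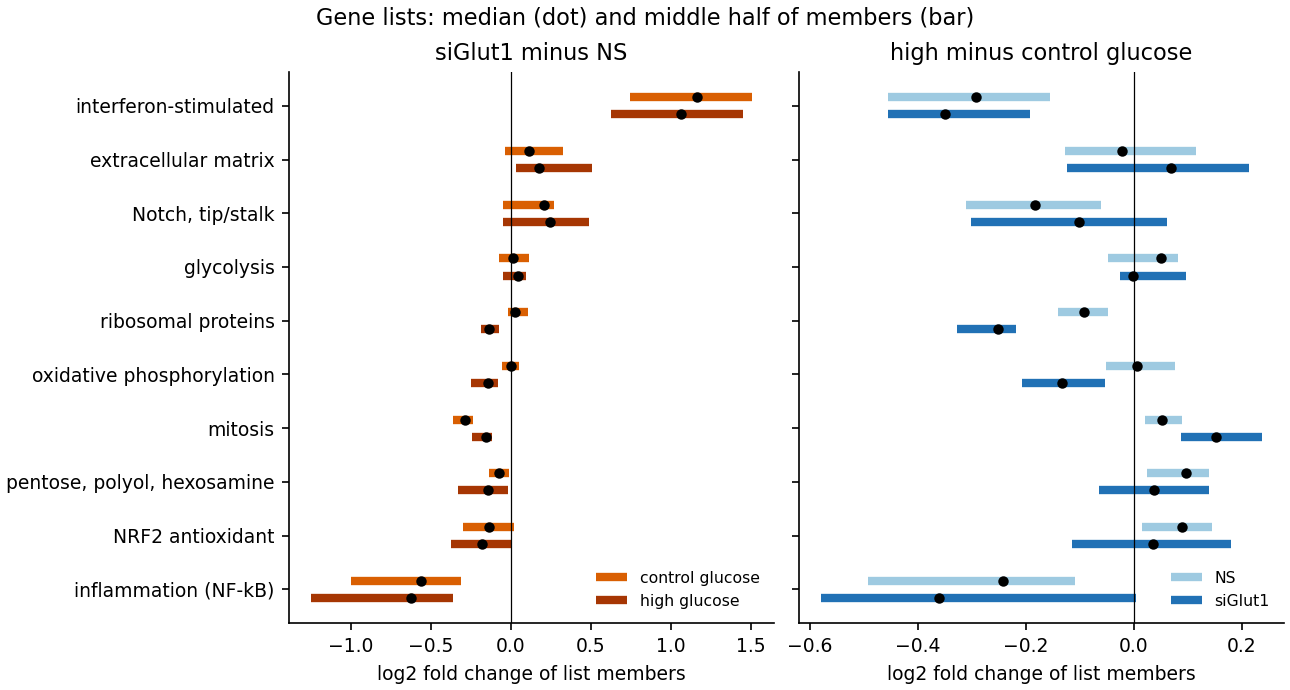
Median (dot) and range between the quartiles (bar) of the log2 fold changes of the members of 10 gene lists, left for siGlut1 against non-silencing siRNA in control and high glucose, right for high against control glucose with either siRNA. Interferon-stimulated genes had the highest medians with siGlut1, 1.16 and 1.06, and NF-kB targets the lowest, -0.56 and -0.62.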

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

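The tests of gene length and of a single library in this part were chosen only after the results were seen.

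The column of non-silencing high 2 stood out because its counts equalled the mean of replicates 1 and 3 in 23397 of 23398 entries, so it carries no measurement of its own. With it counted as a library, siGlut1 changed 825 genes in control and 1807 in high glucose, and high glucose changed 11 genes with non-silencing siRNA and 37 with siGlut1, against 424, 589, 0 and 2 without it.

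For 6 gene lists camera called a difference of the siGlut1 effect between the media, while 0 single genes passed with edgeR (394 at an unadjusted p under 0.05, 0 by DESeq2) and none of the 6 calls held with an estimated correlation. The median interactions on the log2 scale were -0.14 for oxidative phosphorylation (adjusted p = 4.85e-12; adjusted p = 0.387 with an estimated correlation) and -0.16 for ribosomal proteins (adjusted p = 8.81e-18; adjusted p = 0.387 with an estimated correlation). Those of endoplasmic reticulum chaperones, -0.11, cholesterol synthesis, -0.086, NRF2 genes, -0.077, and S-phase genes, 0.14, had adjusted p-values of 0.0237, 0.00493, 0.0386 and 0.0299 (adjusted p = 0.387, 0.575, 0.387 and 0.944 with an estimated correlation). The length correction shrank the first 2 medians to -0.029 (adjusted p = 0.0477) and -0.042 (adjusted p = 0.00529) and ended the chaperone (-0.066, adjusted p = 0.0695) and NRF2 calls (-0.042, adjusted p = 0.234). The NRF2 call also ended without a filter (-0.074, adjusted p = 0.0501) and the S-phase call without both control-glucose replicates numbered 3 (0.12, adjusted p = 0.0508). The cholesterol call ended without non-silencing control 2 (-0.040). The chaperone call ended without non-silencing high 1 (-0.061), siGlut1 high 3 (-0.089), non-silencing control 1 (-0.078) or 2 (-0.091) or siGlut1 control 1 (-0.099). The NRF2 call ended without non-silencing high 1 (-0.039), siGlut1 high 1 (-0.065) or 3 (-0.084), non-silencing control 1 (-0.088) or 2 (-0.074) or siGlut1 control 3 (-0.046). The S-phase call ended without non-silencing high 1 (0.12), siGlut1 high 2 (0.046) or 3 (0.15), non-silencing control 1 (0.11) or siGlut1 control 1 (0.11) or 2 (0.032), and the median was 0.0078 without non-silencing control 3.

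Camera called ribosomal protein and oxidative phosphorylation genes lower in high glucose with siGlut1 (medians -0.25 and -0.13), the same lists as in the interaction, though 0 of 53 and 0 of 48 members passed and neither call held with an estimated correlation (adjusted p = 0.214 and 0.5), and in siGlut1 high-glucose libraries levels rose with gene length. A trend of the libraries on gene length could account for the oxidative phosphorylation genes, whose median became 0.024 (adjusted p = 0.878) once each library's trend was removed. For the ribosomal genes, which are short, the median shrank to -0.10 and the list was still called with the preset correlation (adjusted p = 1.17e-07), so that part of the change stays open between length and the medium. The library whose deviations followed length most, siGlut1 high 1, did not carry the change alone, since the median was -0.23 without it. An effect of high glucose on ribosomal genes stays among the open explanations, as untested, and a difference in RNA quality or library kit that acts through length was not tested.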

How the results depend on the processing

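The 12 columns, the halved counts, the fits without both control-glucose replicates numbered 3 and the length correction were chosen after seeing the data, and the other alternatives before. The counts of changed genes kept within 1.5 times of the reported ones with DESeq2 size factors, no filter, a stricter filter, halved counts and the length correction. With DESeq2 the counts were 1049 for siGlut1 in control glucose, 1319 for siGlut1 in high glucose, 33 for high glucose with non-silencing siRNA, 432 with siGlut1 and 541 for the average of high glucose. With only the groups compared in the fit they were 70 for siGlut1 in control glucose, 1157 in high glucose and 0 for high glucose with siGlut1, and the fewer libraries give a less certain spread. With a fold minimum of 2, 51, 90 and 0 genes were left in these 3 comparisons. With 12 columns the counts were 825, 11, 1807 and 37 in the 4 pairwise comparisons, 3184 for the average of siGlut1 and 428 for that of high glucose, since the averaged column lowers the spread. Without both control-glucose replicates numbered 3 they were 247, 48, 1672, 734 and, for the average of high glucose, 2580, and SLC2A1 passed the threshold for high glucose on average (-0.30). The interaction stayed at 0 genes in each alternative, DESeq2 included, with 394 at an unadjusted p under 0.05. Where the cause is not given, the cause was not tested.

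With 1 library left out at a time, counts ranged from 135 to 316 for siGlut1 in control glucose, 6 to 261 in high glucose, 0 to 2 for high glucose with non-silencing siRNA and were 0 in each fit with siGlut1, with 1 library less per fit. The averages ranged from 1001 to 2500 for siGlut1 and from 0 to 850 for high glucose. The correlation of the siGlut1 effects between media ranged from 0.333 to 0.561 and that of the high glucose effects from 0.163 to 0.367. The relation of both average effects ranged from -0.443 to 0.101 and turned positive without non-silencing control 3 (0.10), siGlut1 high 1 (0.011) or 3 (0.058) or both control-glucose replicates numbered 3 (0.036). The r between media was 0.10 without a filter and 0.76 with a stricter one, and that between siRNAs 0.064, 0.57 and, without both replicates numbered 3, 0.45. The cause was not tested.

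Of 38 list calls in the pairwise comparisons, 0 held with an estimated correlation and 15 by fry. Over all 7 comparisons with averages and interaction, 54 of 66 list calls held after the length correction, where the oxidative phosphorylation median reversed to 0.024 with siGlut1 and 0.044 on average in high glucose, and 56 of 66 without both replicates numbered 3, where matrix genes reversed to -0.024 on average in high glucose. Single libraries reversed mitosis genes in high glucose with non-silencing siRNA (-0.097 without non-silencing control 2, up to 0.23) and S-phase genes in the interaction (0.0078 without non-silencing control 3, up to 0.26), by the direction camera gives. Of 208 calls of named genes, 208 held with DESeq2 and with 12 columns, 206 with halved counts, 198 with DESeq2 size factors, 195 without a filter, 191 without both replicates numbered 3 and 182 after the length correction. Of those a stricter filter kept, 201 of 205 held, and 68 of 95 with only 2 groups. Most were lost without non-silencing high 1 (101 of 167) or 3 (97 of 167), and 0 reversed. With 40135082 to 90536476 counts per library, CCL20 and others near the floor rest on few counts, and whether more libraries or more depth would add calls was not compared.

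The replicate number as a block gave 561, 0, 600 and 3 genes in the pairwise comparisons, 0 for the interaction, and 2190 and 59 for the averages. Of the genes called without it, the block kept 391 of 424 and 467 of 589 with siGlut1 in control and high glucose. In the averages it kept 1871 of 2065 with siGlut1 and 40 of 59 with high glucose. It gave 39 list calls and correlations of 0.533, 0.295 and -0.0777. SLC2A1 changes were -1.59, -0.14, -1.65, -0.20, -0.06, -1.62 and -0.17, with no SLC2A1 call changed. With the block, 15 of 208 named genes and 7 of 66 list calls no longer passed. It ended the list calls of NF-kB (-0.059), Notch (-0.11) and mitosis genes (-0.0053) in high glucose with non-silencing siRNA, of mitosis genes with siGlut1 in high glucose (-0.085), and of TCA cycle (-0.071), chaperone (-0.090) and cholesterol genes (-0.067) in the siGlut1 average. NF-kB genes past the threshold rose from 2 to 8 and from 2 to 11 with siGlut1 in control and high glucose, and from 12 to 22 on average. The labels give no pairing. In their deviations from the group means, libraries with the same number correlated at 0.0930, 0.353 and 0.535 between the control-glucose groups, at 0.231 and 0.192 between the high-glucose groups and at -0.250 to 0.239 across media. Not every pair was over 0.1, and non-silencing control 1 correlated more with siGlut1 control 2 (0.147) than with its own number, so the numbers were not taken to pair the samples, though all same-number pairs within a medium were positive.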

Other observations

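The splits of the samples and the position test of the control labels were planned before their results were seen, and the other tests in this part were chosen only after the results were seen.

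Averaged over both media, 2065 of 14324 genes passed the threshold with siGlut1, and single genes of lipid, sugar and amino acid use were among those that passed in neither medium alone. HILPDA, which restrains fat breakdown at lipid droplets, rose by 0.45 ± 0.08 SE (adjusted p = 0.00572), the glucose transporter SLC2A12 by 0.31 (adjusted p = 0.0359) and the glycolytic enzyme PFKP by 0.22 (adjusted p = 0.0165). MDH1 and SUCLG2, enzymes that handle malate and succinyl-CoA, fell by 0.29 (adjusted p = 0.00776) and fell by 0.32 (adjusted p = 0.00927), and GNPNAT1 of the hexosamine pathway fell by 0.36 (adjusted p = 0.0152). PSAT1, which makes serine, fell by 0.36 (adjusted p = 0.0152) and DDIT4, a stress-induced inhibitor of mTOR, fell by 0.55 (adjusted p = 0.0334). In this average 4 of 22 TCA cycle genes, 5 of 17 pentose, polyol and hexosamine genes and 4 of 30 stress response genes were lower (camera adjusted p = 0.0283, 0.00217 and 0.107; adjusted p = 0.521, 0.153 and 0.681 with an estimated correlation). The TCA cycle call ended without non-silencing high 1 (-0.058), siGlut1 high 1 (-0.0798) or non-silencing control 3 (-0.063). It also ended with the replicate block (-0.071) and after the length correction (-0.0796). Without non-silencing high 1 the calls of PFKP (0.19), SUCLG2 (-0.27), GNPNAT1 (-0.35) and PSAT1 (-0.36) ended, the last 2 also without non-silencing high 3 (-0.36 and -0.36). Those of SLC2A12 (0.27 to 0.37) and DDIT4 (-0.44 to -0.58) ended without any 1 of 9 and 8 libraries.

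Single genes of vessels, junctions, tip cells and matrix moved in the same average. Neither the endothelial identity list nor the junction list was called. Camera did call the Notch and tip or stalk list, as given above, though not with an estimated correlation. CLEC14A, an endothelial lectin, rose by 0.60 ± 0.11 SE (adjusted p = 0.00417), the endothelial adhesion protein MCAM by 0.19 (adjusted p = 0.0085), APLN, a tip cell peptide, by 0.29 (adjusted p = 0.0114) and the collagen COL5A1 by 0.61 (adjusted p = 0.00646). F11R, a junctional adhesion molecule, fell by 0.36 (adjusted p = 0.0107), a call that ended without non-silencing high 1 (-0.32). Of 29 endothelial identity genes 8 were higher and 1 lower in the average (camera adjusted p = 0.102; adjusted p = 0.725 with an estimated correlation), and of 22 junction genes 2 and 2 (adjusted p = 0.941; adjusted p = 0.977).

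Interferon-stimulated genes were higher with siGlut1 in both media, with a median average effect of 1.16. The tables argue against a gene length trend, since the median was 1.18 once each library's trend was removed, with 34 of 35 genes past the threshold. They also argue against the control-glucose replicates numbered 3 as the whole cause, since in high glucose, which holds neither, the median was 1.06, and without them it was 1.04 on average with 32 of 35 past the threshold, though in control glucose it went from 1.16 to 0.94 and the members past the threshold from 24 to 8. Cells can sense an siRNA duplex as foreign RNA, but both groups compared received an siRNA, so a response common to both would cancel. A response particular to the siGlut1 duplex stays open as a candidate explanation beside suppression of Glut1. The median interaction was -0.051, so the rise was alike in both media. A rise that added glucose took back would have argued against a response to the duplex, and this was not seen. The alike rise does not decide between the explanations, since suppression of Glut1 could also act alike in either medium. The labels name no untransfected cells and no second siRNA against SLC2A1, so that these explanations cannot be told apart.

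More genes changed with high glucose when the control-glucose replicates numbered 3 were left out, 2580 for the average effect against 59, and since these libraries were picked by how they stood in the data, the 2580 may be inflated. Leaving out any other pair of 1 control-glucose library per siRNA gave at most 261 genes, so the gain was largest for this pair. The pairs that gave 250 and 261 genes also held non-silencing control 3, and pairs without it gave 0 to 16. Leaving out non-silencing control 3 alone gave 850 genes, and siGlut1 control 3 alone 25. The replicate block gave 59, which argues against a shift of the same size in all replicates numbered 3. Their deviations from the group means correlated at 0.535 between the control-glucose groups and at 0.0855 to 0.192 for the other pairs numbered 3. A shared batch of unequal size therefore stays open. Positions were taken on the glucose effect measured with the other siRNA over 11464 genes. There 0 stands for the other control-glucose libraries and 1 for the high-glucose ones. Non-silencing control 3 lay at 1.29 and siGlut1 control 3 at 0.854, near the high-glucose libraries (0.856 to 1.14). The other control-glucose libraries lay apart from them (-0.453 to 0.312). No measured high-glucose library lay at the control position, so none of them was a partner for a swap between the groups. The left-out non-silencing high-glucose column holds no measurement of its own. A swap between non-silencing control 3 and the library behind that column therefore could not be tested. Against high-glucose cells under a control label, glucose-induced TXNIP was at 83.9 CPM in non-silencing control 3, against 226 to 304 CPM in high glucose. With siGlut1 it does not separate the media, with 75.8, 96.4 and 122 CPM in control against 94.6 to 150 CPM in high glucose. Of glucose genes taken from the other siRNA, 63.6% of 44 lay nearer the high-glucose mean in siGlut1 control 3. That share was 95.2% to 100% in its high-glucose libraries, and 0% and 2.33% in the other siGlut1 control libraries. In non-silencing control 3 it was 87.9% of 531. The non-silencing high-glucose libraries gave 87.5% to 93.3%, and the other non-silencing control libraries 14.6% and 2.30%. Both positions met the criterion set beforehand for a wrong control label. Of the checks chosen after the results were seen, the share in non-silencing control 3 went the same way. TXNIP in non-silencing control 3 and the share of 63.6% in siGlut1 control 3 did not. A culture state or batch that resembles high glucose would also give such positions. It cannot be told apart from a wrong control label, and no library was moved to another group.

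Splits of the libraries into other groups asked whether chance alone gives as many genes. For siGlut1 in control glucose (424 genes) and high glucose with siGlut1 (2 genes), the highest of the other 9 splits gave 0 genes in each case, 1 of 10 splits reaching the real count, and 10 splits are too few for a share under 0.05. For the average siGlut1 effect, 1 of 40 drawn splits, the real one, reached 2065 genes and the highest other gave 703. The real split was always among the 40, drawn from 200 possible splits, so 1 of 40 is the smallest share this test can give. None of the other drawn splits gave as many genes, which does not exclude chance, and the samples may not be separate cultures. For the average high glucose effect, 2 of 40 splits reached 59 genes, so that chance is not excluded. The other one gave 1543 genes and put both control-glucose replicates numbered 3 with non-silencing high 1 and 3 and siGlut1 high 2 and 3, which points to a structure of the samples. Groups of 2 against 3 were not split.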
